A study of Mus musculus with 22 samples.

How the data were processed

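Whole-lung RNA from 22 mice was sequenced, per the labels from libraries made with a stranded TruSeq mRNA kit and read on a NextSeq 500. The table deposited by the authors holds expected counts per gene from RSEM, and their processing notes also name Trimmomatic, STAR and the GRCm38 build, without versions. Expected counts divide reads that fit several genes between them, so values of near-identical genes (globins, Hspa1a and Hspa1b, Klra genes, immunoglobulin genes) are uncertain. The table has 54532 genes, of which 54495 identifiers are in the GENCODE M21 annotation of GRCm38, used for coordinates.

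Groups were taken from the sample titles. In 3 libraries the treatment tag named the other treatment, and results without these 3 and with treatment read from the tag are given as alternatives. Replicate numbers follow the order of the samples and pair none of them. No 2 libraries of a group agreed within sampling noise (chi-square per gene from 5.35 to 39), and each was counted as 1 replicate.

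Expected counts were rounded to whole numbers. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10), leaving 16638. TMM factors and the robust quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) were applied in one fit of all 4 groups, and p values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Tests are two-sided. Log2 fold changes carry standard errors equal to their size divided by the square root of F. The 7 contrasts were hypoxia in each treatment, ABT-263 in each oxygen condition, the interaction, ABT-263 averaged over oxygen conditions, and hypoxia with ABT-263 against normoxia with vehicle. Levels are edgeR's CPM, counts scaled to a common library total with TMM factors, as mean ± SD. Library totals were 11509007 to 15744193 counts, and the median standard error of a log2 fold change was 0.11 for hypoxia with vehicle and 0.16 for the interaction.

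Of 44 gene lists fixed before the data were examined, 43 had at least 5 tested genes and were tested with camera (preset correlation 0.01), with camera with an estimated correlation, and with fry, which does not compare a list with other genes. List p values are adjusted over the 43 lists. A count adjusted over the list alone uses the p values of its members. A list p given without mention of an estimated correlation used the preset one. Lists share some genes. Scores per library are the mean log2 CPM (prior count 2) of a list's tested members.

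Genes named in the text follow a rule fixed before the data were examined: for each contrast the 12 largest changes in each direction among genes that passed, with at least 2 CPM in the higher group and without gene models and immunoglobulin or T cell receptor segments, and up to 4 members with the smallest p of each list described. If none passed, the 5 smallest p values were used. Cdkn2a, Cdkn1a, Bcl2, Bcl2l1, Bcl2l2 and Bmpr2 were named whatever their values. A part of the genes taken by the rule is printed. Genes given per library were chosen after their values were seen.

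Whether ABT-263 ran against hypoxia was measured as the correlation across genes of log2 fold changes. The hypoxia vehicle libraries were divided between the contrasts in 20 ways. The correlation with undivided libraries was compared with 20 simulations without any effect of hypoxia or ABT-263. Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals without TMM, no low-count filter, at least 1 CPM in at least 4 libraries, a fit of the compared groups only, haemoglobin genes left out, an added 2-fold threshold, each library left out in turn, and the label alternatives. Leaving out normoxia ABT-263 replicates 2 and 6 together was added after the data were examined. For each contrast up to 100 groupings of the libraries, the real one included, were fitted. Figures were drawn with matplotlib 3.10.9.

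The fits were tested on simulated counts with changes of known size. For ABT-263 in normoxia, 76.1% of 1.5-fold, 87.5% of 2-fold and 98.5% of 4-fold changes were recovered, with 14 unchanged genes called. For ABT-263 in hypoxia the shares were 59.7%, 93.8% and 100%, with 9 unchanged genes called. In a simulation of 44 lists, camera called the list of raised genes and none of the others under either correlation. Simulated genes varied independently, whereas the cell cycle list had an estimated correlation of 0.85 for ABT-263 in normoxia. The simulation therefore does not show how the preset correlation behaves for genes that move together.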

Results

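RNA was sequenced from the lungs of 22 male C57BL/6J mice kept for 8 days in normoxia or in hypoxia. Mice received vehicle or ABT-263 (navitoclax) at 50 mg/kg per day. ABT-263 inhibits the anti-apoptotic proteins BCL-2, BCL-XL and BCL-W and is used to remove senescent cells. The groups held 5 normoxia vehicle, 6 normoxia ABT-263, 6 hypoxia vehicle and 5 hypoxia ABT-263 libraries. Totals ran from 11509007 to 15744193 counts per library, and 16638 genes were tested. For 3 libraries, replicate 1 of the normoxia ABT-263, hypoxia vehicle and hypoxia ABT-263 groups, the sample title and the treatment tag named different treatments. Groups follow the titles throughout. The first principal component held 30.6% of the variance and had normoxia libraries on one side (highest −4.07) and hypoxia libraries on the other (lowest 11.4). The second held 14.5%, with its highest values in normoxia ABT-263 replicates 2 (32.8) and 6 (24.2), hypoxia ABT-263 replicate 4 (14.2) and normoxia ABT-263 replicate 1 (12.4).

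The first comparison asked what 8 days of hypoxia changed in the lungs of vehicle-treated mice. By camera with its preset correlation, hypoxia lowered the lists of general capillary endothelium and lymphocytes, and raised those of pericytes, smooth muscle, extracellular matrix and erythroid cells. With an estimated correlation none of these was called except, by a narrow margin, the plasma cell list. Among the largest rises were Olfr78, an odorant-type receptor (log2 fold change 4.24 ± 0.33 SE), Ntrk2, the receptor of brain-derived neurotrophic factor (3.89 ± 0.16), the phosphatase Ptprr (3.30 ± 0.15), the soluble pattern recognition protein Ptx3 (3.25 ± 0.24) and the hyaluronan-binding protein Cemip (2.91 ± 0.25). Among the largest falls were Ankrd63 (−4.85 ± 0.20), the xenobiotic-metabolising enzyme Cyp1a1 (−3.52 ± 0.66), Olfm2 (−3.08 ± 0.26), Plvap, the diaphragm protein of endothelial fenestrae and caveolae (−2.50 ± 0.17), the growth factor-binding protein Igfbp3 (−2.26 ± 0.16), the Notch ligand Dll4 (−1.94 ± 0.10) and the endothelial proteoglycan Esm1 (−1.80 ± 0.22). Ntrk2 (ENSMUSG00000055254; GRCm38 chromosome 13, 58806569 to 59133970) went from 11 ± 1.71 CPM (SD, n = 5) to 163 ± 20.8 CPM (SD, n = 6). Plvap (ENSMUSG00000034845; GRCm38 chromosome 8, 71497765 to 71511752) went from 499 ± 91.4 to 88 ± 15.9 CPM. In all, 4380 genes passed edgeR's quasi-likelihood test at an adjusted p under 0.05, 2251 higher and 2129 lower in hypoxia. Of these, 270 rose and 165 fell by at least 2-fold. The count lay between 3319 and 4606 with each library left out in turn.

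Among 13 pericyte genes 8 rose and none fell, with Higd1b at 1.62 ± 0.12, Rgs5 at 1.53 ± 0.16 and Cspg4 at 1.14 ± 0.12 (camera adjusted p = 6.46e-08, and adjusted p = 0.0641 with an estimated correlation). Of 19 smooth muscle genes 10 rose, among them the actin-binding proteins Tagln (1.11 ± 0.11) and Cald1 (0.72 ± 0.08), and none fell (adjusted p = 1.49e-07, and adjusted p = 0.0972 with an estimated correlation). Of 37 extracellular matrix genes 21 rose and 1 fell, with Mfap4 at 1.63 ± 0.14, Col8a1 at 1.69 ± 0.19 and the collagen cross-linking enzyme Lox at 1.30 ± 0.15 (adjusted p = 2.39e-12, and adjusted p = 0.214 with an estimated correlation). Adjusted over the list alone, 9 pericyte, 11 smooth muscle and 21 extracellular matrix genes were higher. Targets of hypoxia-inducible factor rose in 13 of 34 cases and fell in 2. Examples were the mitophagy receptors Bnip3 (1.21 ± 0.10) and Bnip3l (0.46 ± 0.07), and this list kept its call by a narrow margin (adjusted p = 0.0495 with an estimated correlation). Adjusted over the list alone, 14 targets were higher and 2 lower. Erythroid genes rose in 13 of 20 cases, including the near-identical globin copies Hbb-bs (1.41 ± 0.18) and Hbb-bt (1.47 ± 0.17), between which reads are divided (adjusted p = 7.54e-12, and adjusted p = 0.0972 with an estimated correlation). Haemoglobin genes took 0.473% ± 0.0602 of all counts (SD, n = 5) in normoxia vehicle and 1.15% ± 0.13 (SD, n = 6) in hypoxia vehicle libraries.

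Endothelial lists moved in both directions. Of 11 general capillary genes 7 fell, including Bmp6 (−1.41 ± 0.15), and 2 rose, including the chemokine Cxcl12 (1.26 ± 0.16), and the list was lower (adjusted p = 0.000924, and adjusted p = 0.147 with an estimated correlation). The list of aerocytes, the second capillary type, was not called (6 of 14 genes lower, 2 higher, adjusted p = 0.0579, and adjusted p = 0.645 with an estimated correlation), and 7 were lower and 2 higher adjusted over the list alone. Among 24 pan-endothelial genes 10 fell, including the co-receptor Eng (−1.26 ± 0.12), and 5 rose, including Emcn (1.06 ± 0.09) (adjusted p = 0.00213, and adjusted p = 0.689 with an estimated correlation). Of 14 artery genes 4 fell, with Efnb2 at −1.12 ± 0.13 and Hey1 at −1.12 ± 0.13, and 6 rose, and the list was not called (adjusted p = 0.584). The BMP and TGF-beta list was divided as well, with 7 of 27 genes higher and 7 lower (adjusted p = 0.778). Bmpr2, whose loss-of-function variants cause heritable pulmonary arterial hypertension (ENSMUSG00000067336; GRCm38 chromosome 1, 59763400 to 59879014), fell from 267 ± 24.8 to 174 ± 17.8 CPM (−0.62 ± 0.12, adjusted p = 0.000321). The activin antagonist Fst rose (2.02 ± 0.21).

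Leukocyte markers were mostly lower in hypoxia. Of 23 B cell genes 22 fell, as did 17 of 23 T cell genes, 17 of 22 NK and cytotoxic genes and 6 of 10 plasma cell genes, and none of these 4 lists had a member that rose. Adjusted over the list alone, 22, 19, 20 and 8 were lower. Examples were the B cell receptor component Cd79a (−1.16 ± 0.12), the T cell receptor chain Trac (−0.92 ± 0.14) and the cytokine receptor Il2rb (−1.27 ± 0.15). Camera's adjusted p values were 2.79e-22, 7.8e-11, 2.39e-12 and 0.00091. In the same order the lists had an adjusted p = 0.0641, 0.0972, 0.147 and 0.0495 with an estimated correlation. The plasma cell list alone among these kept its call, by a narrow margin. Of 24 platelet and megakaryocyte genes 15 fell and 2 rose (adjusted p = 4.77e-06, and adjusted p = 0.32 with an estimated correlation), and of 21 neutrophil genes 9 fell and 2 rose (adjusted p = 0.00175, and adjusted p = 0.43 with an estimated correlation). Alveolar macrophage genes were higher in 8 of 22 cases and lower in 1, with Chil3 at 1.11 ± 0.17 (adjusted p = 0.000299, and adjusted p = 0.32 with an estimated correlation).

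In vehicle-treated mice senescence regulators were not called as a list in hypoxia (4 of 18 higher, 2 lower, adjusted p = 0.778), and neither were senescence-associated secreted factors (12 of 49 higher, 7 lower, adjusted p = 0.208). Members that passed included Pgf (1.47 ± 0.13), Vegfc (1.30 ± 0.13) and the chemokine Ccl5 (−1.14 ± 0.14). Cdkn1a, which encodes the cell cycle inhibitor p21, did not pass (0.19 ± 0.16, adjusted p = 0.414). Cdkn2a, the p16 gene, had 2 to 15 counts per library, too few to be tested, at 0.618 ± 0.162 CPM in normoxia vehicle, 0.693 ± 0.284 CPM in normoxia ABT-263, 0.382 ± 0.192 CPM in hypoxia vehicle and 0.44 ± 0.0815 CPM in hypoxia ABT-263 libraries. Of the targets of ABT-263, Bcl2 rose slightly (0.25 ± 0.09, adjusted p = 0.0372), and Bcl2l1 (0.16 ± 0.11) and Bcl2l2 (0.25 ± 0.11) did not pass.

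**Figure D1:**
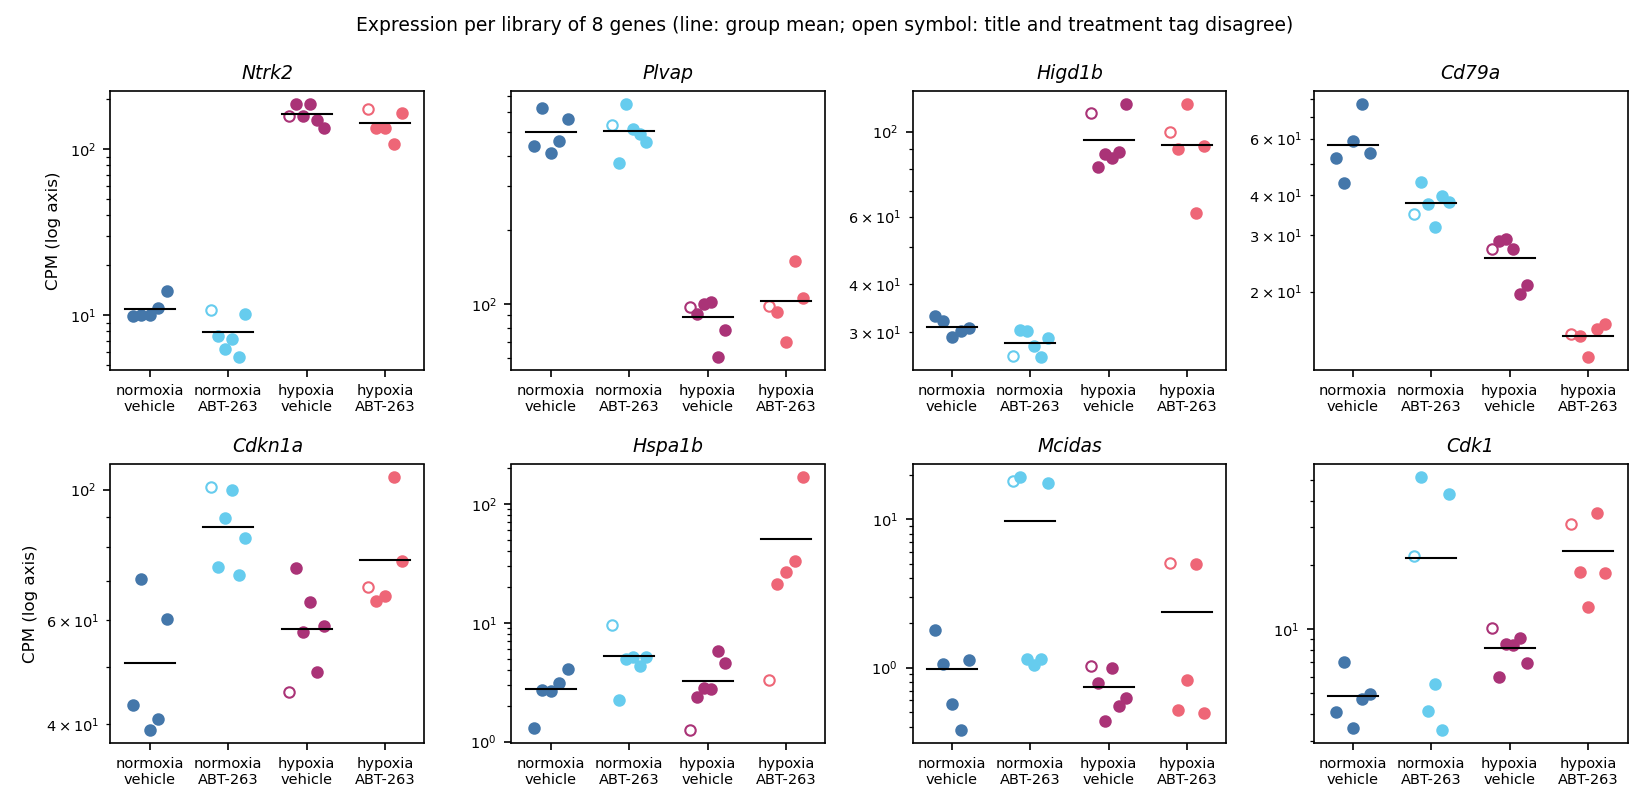
CPM (log axis) of 8 genes in each of the 22 libraries, by group; points are libraries, lines are group means, and open symbols mark the 3 libraries whose title and treatment tag differ. Ntrk2 averaged 11 CPM in normoxia vehicle and 163 CPM in hypoxia vehicle libraries, and Mcidas was highest in 5 ABT-263 libraries (5.02 to 19.2 CPM).

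The second comparison asked what ABT-263 changed in normoxia. ABT-263 lowered lymphocyte transcripts, and 71 of the 89 genes that passed were lower and 18 higher. Of 23 B cell genes 13 fell, as did 8 of 23 T cell genes and 7 of 22 NK and cytotoxic genes, with no member rising. The falls included the B cell surface proteins Ighd (−0.83 ± 0.12) and Cd22 (−0.74 ± 0.13), the T cell proteins Cd5 (−0.91 ± 0.16) and Cd3e (−0.83 ± 0.18), and the NK cell receptors Klrd1 (−0.76 ± 0.16) and Klra9 (−1.30 ± 0.26). Klra9 belongs to a family of close copies and its value is uncertain. Adjusted over the list alone, 23 B cell, 21 T cell and 21 NK and cytotoxic genes were lower. The lists held with an estimated correlation (adjusted p = 0.0078, 0.00727 and 0.0181). Cd22 (ENSMUSG00000030577; GRCm38 chromosome 7, 30865402 to 30880342) was at 31.7 ± 6.33 CPM with vehicle (SD, n = 5) and 19 ± 2.68 CPM with ABT-263 (SD, n = 6).

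Genes that rose with ABT-263 in normoxia were led by Syt12 (1.27 ± 0.28), the platelet tubulin Tubb1 (0.94 ± 0.20), Cdkn1a (0.77 ± 0.16, adjusted p = 0.0328) and the serotonin transporter Slc6a4 (0.76 ± 0.15). Cdkn1a (ENSMUSG00000023067; GRCm38 chromosome 17, 29090976 to 29100727) was at 50.8 ± 13.9 CPM with vehicle and 86.5 ± 12.7 CPM with ABT-263. Of 24 platelet and megakaryocyte genes 1 rose over all genes and 12 were higher adjusted over the list alone (adjusted p = 5.05e-10, and adjusted p = 0.267 with an estimated correlation). With edgeR none of 40 cell cycle genes passed over all genes, 24 were higher adjusted over the list alone, and the list had a median log2 fold change of 1.07 (adjusted p = 1.03e-12, and adjusted p = 0.617 with an estimated correlation). Without normoxia ABT-263 replicates 2 and 6 that median was −0.00728 (adjusted p = 0.889). Neither the senescence regulators (1 of 18 higher, adjusted p = 0.0508, and adjusted p = 0.617 with an estimated correlation) nor the secreted factors (1 of 49 lower, adjusted p = 0.251, and adjusted p = 0.813 with an estimated correlation) were called. Bcl2 (−0.11 ± 0.09), Bcl2l1 (0.32 ± 0.11), Bcl2l2 (0.15 ± 0.10) and Bmpr2 (0.02 ± 0.12) did not pass.

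The count of 89 depended on single libraries and on the labels. It ran from 1 to 183 with each library left out in turn. Leaving out vehicle replicate 4 or ABT-263 replicate 4 gave 1 gene each, and ABT-263 replicate 1 gave 2. Vehicle replicates 3, 5 and 2 gave 21, 58 and 183, and ABT-263 replicate 2 gave 144. It was 16 without the 3 libraries with conflicting labels, of which 16 were among the 89. With treatment read from the tag it was 0 with edgeR, with 1386 genes at an unadjusted p under 0.05. By their B cell scores, given below, the 3 libraries with conflicting labels went with their titles. DESeq2 called 324 and limma-voom 109 with the title groups, and neither was run with the tags.

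The third comparison asked what ABT-263 changed in hypoxia. B cell transcripts were again lower and some heat shock transcripts higher, among 50 genes that passed (19 higher, 31 lower). Of 23 B cell genes 11 fell, including Cd79a (−0.81 ± 0.13), Cd22 (−0.80 ± 0.14) and the IgM receptor Fcmr (−0.87 ± 0.15), and the list held with an estimated correlation (adjusted p = 0.0202). Adjusted over the list alone, 21 were lower. Cd79a (ENSMUSG00000003379; GRCm38 chromosome 7, 24897381 to 24902197) was at 25.5 ± 4.07 CPM with vehicle (SD, n = 6) and 14.6 ± 1.24 CPM with ABT-263 (SD, n = 5). In the T cell list and in the NK and cytotoxic list 1 gene each fell, in the latter the kinase Txk (−0.97 ± 0.20), and 4 and 6 were lower adjusted over the list alone. These lists had adjusted p values of 2.69e-07 and 7.73e-10 and lost the call (adjusted p = 0.399 for each with an estimated correlation).

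Of 24 heat shock and unfolded protein genes 3 rose, the chaperones Hspa1b (3.96 ± 0.69), Hspa1a (3.79 ± 0.70) and Dnajb1 (1.42 ± 0.25). Hspa1a and Hspa1b are near-identical copies between which reads are divided. The list was called (adjusted p = 5.57e-09) but had an adjusted p = 0.399 with an estimated correlation. Hypoxia with vehicle had lowered this list (6 of 24 lower, 0 higher, adjusted p = 0.04, and adjusted p = 0.758 with an estimated correlation). Its score was 5.87 to 6.29 in normoxia vehicle, 5.77 to 5.96 in hypoxia vehicle and 5.81 to 7.04 in hypoxia ABT-263 libraries. Hspa1b (ENSMUSG00000090877; GRCm38 chromosome 17, 34956436 to 34959238) stood at 3.32, 21.3, 26.8, 33.2 and 168 CPM in ABT-263 replicates 1 to 5, against 1.25 to 5.74 CPM in the 6 vehicle libraries. Other genes that rose were the death receptor Tnfrsf10b (0.76 ± 0.16) and Sema7a (0.65 ± 0.14). Cell cycle genes had a median of 1.17, with none of 40 passing over all genes and 33 higher adjusted over the list alone (adjusted p = 4.5e-22, and adjusted p = 0.417 with an estimated correlation). Of 37 extracellular matrix genes none passed, and their median was 0.20 (adjusted p = 1.65e-07, and adjusted p = 0.494 with an estimated correlation). Senescence-associated secreted factors were called as higher, with a median of 0.15 and with none of 49 passing by edgeR either over all genes or adjusted over the list alone (adjusted p = 0.00653, and adjusted p = 0.494 with an estimated correlation). Senescence regulators were not called (adjusted p = 0.0502, and adjusted p = 0.505 with an estimated correlation). The glucose transporter Slc2a1 fell (−0.53 ± 0.11), 1 of 34 targets of hypoxia-inducible factor over all genes, and 2 were lower adjusted over the list alone (adjusted p = 0.08, and adjusted p = 0.486 with an estimated correlation). Cdkn1a (0.39 ± 0.16, adjusted p = 0.276), Bcl2 (0.06 ± 0.09), Bcl2l1 (0.19 ± 0.11), Bcl2l2 (−0.10 ± 0.10) and Bmpr2 (0.02 ± 0.12) did not pass.

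This count of 50 also moved with single libraries, from 3 to 228. Leaving out ABT-263 replicates 1, 2, 4 and 5 gave 228, 28, 5 and 4 genes, and vehicle replicates 1 to 4 gave 11, 3, 26 and 11. Normoxia vehicle replicate 5 gave 32 and normoxia ABT-263 replicate 2 gave 83. Without the 3 libraries with conflicting labels the count was 77, of which 31 were among the 50. With treatment read from the tag it was 0 with edgeR, with 1650 genes at an unadjusted p under 0.05. DESeq2 called 247 and limma-voom 9 with the title groups, and neither was run with the tags. With library totals in place of TMM factors 20 genes were higher and 16 lower.

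Averaged over both oxygen conditions, ABT-263 changed 423 genes, 205 higher and 218 lower. Of 23 B cell genes 21 fell, as did 13 of 23 T cell genes and 15 of 22 NK and cytotoxic genes, and these lists held with an estimated correlation (adjusted p = 0.0016, 0.00968 and 0.0239). Adjusted over the list alone, 23, 21 and 20 were lower. Ighd (−0.99 ± 0.09), Cd22 (−0.77 ± 0.10), Cd5 (−0.66 ± 0.12), Txk (−0.89 ± 0.14) and the cytotoxic cell protease Ctsw (−0.88 ± 0.15) were among them. Glucocorticoid targets were higher (2 of 18 rose over all genes and 11 were higher adjusted over the list alone, adjusted p = 0.0489 with an estimated correlation), with Klf9 at 0.38 ± 0.10. Cdkn1a, which is on that list and on the p53 list, rose (0.58 ± 0.12, adjusted p = 0.00997), as did the p53 target Tnfrsf10b (0.54 ± 0.11). The p53 list was called (2 of 24 higher, adjusted p = 0.0125, and adjusted p = 0.197 with an estimated correlation). Senescence regulators, a list that holds Cdkn1a, were called as higher (1 of 18 rose and 4 were higher adjusted over the list alone, adjusted p = 0.00897, and adjusted p = 0.416 with an estimated correlation). Their score in normoxia ABT-263 replicate 6 stood apart from its group (5.26, others 5.07 to 5.13). Secreted factors were not called (1 of 49 lower, adjusted p = 0.463, and adjusted p = 0.987 with an estimated correlation). With edgeR none of 20 erythroid genes passed, and the list was not called (adjusted p = 0.923). Slc6a4 rose (0.52 ± 0.11). Bcl2 (−0.03 ± 0.06), Bcl2l1 (0.26 ± 0.08), Bcl2l2 (0.02 ± 0.07) and Bmpr2 (0.02 ± 0.08) did not pass.

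Among the largest rises averaged over oxygen conditions, beside Hspa1b (2.45 ± 0.52) and Hspa1a (2.31 ± 0.52), were genes that act in precursors of multiciliated cells, Mcidas (2.50 ± 0.64), Foxn4 (2.02 ± 0.51) and Ccno (1.90 ± 0.49), and the mitotic genes Ccnb1 (1.99 ± 0.47), Cdk1 (1.83 ± 0.42) and Cenpf (1.68 ± 0.38). Of 40 cell cycle genes 13 rose over all genes and 38 were higher adjusted over the list alone (adjusted p = 2.33e-27, and adjusted p = 0.274 with an estimated correlation). Not all treated mice shared the rise of Mcidas (ENSMUSG00000074651; GRCm38 chromosome 13, 112993845 to 113000394), which was at 18.2, 19.2 and 17.5 CPM in normoxia ABT-263 replicates 1, 2 and 6 and at 5.05 and 5.02 CPM in hypoxia ABT-263 replicates 1 and 4. It lay between 0.496 and 1.15 CPM in the other 6 ABT-263 libraries and between 0.379 and 1.78 CPM in the 11 vehicle libraries. In hypoxia Cdk1 was at 12.7 to 34.9 CPM in the 5 ABT-263 libraries, all above the 6 vehicle libraries (5.94 to 10.1 CPM). In normoxia Cdk1 was at 51.5 and 42.8 CPM in ABT-263 replicates 2 and 6, at 21.9 CPM in replicate 1, at 3.37 to 5.52 CPM in replicates 3 to 5 and at 3.43 to 7.04 CPM in the 5 vehicle libraries.

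The count of 423 was 285 without the 3 libraries with conflicting labels, of which 218 were among the 423. With treatment read from the tag it was 0 with edgeR, with 1916 genes at an unadjusted p under 0.05, and DESeq2 and limma-voom, which called 793 and 253 with the title groups, were not run with the tags. It lay between 164 and 649 with each library left out. It moved by over 1.5 times without normoxia vehicle replicates 1 (207), 3 (173), 4 (186) and 5 (255), normoxia ABT-263 replicates 1 (231) and 6 (214), hypoxia vehicle replicates 1 (215), 2 (235) and 6 (232) and hypoxia ABT-263 replicates 1 (649), 4 (164) and 5 (187).

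**Figure D2:**
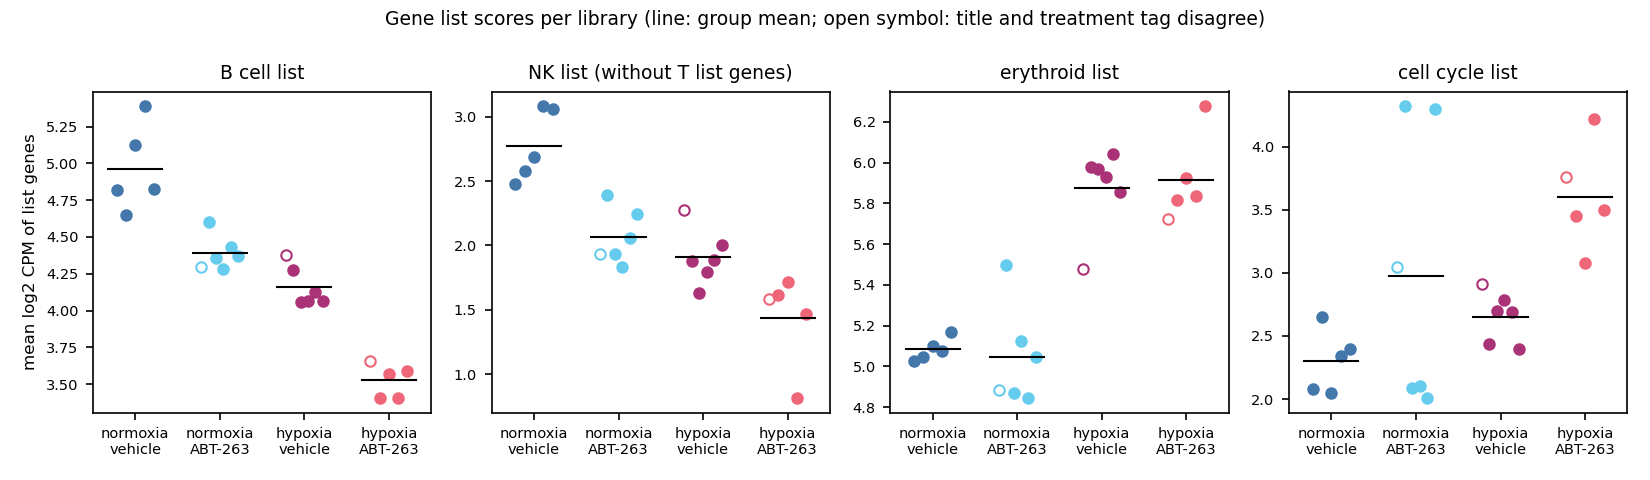
Mean log2 CPM of the genes of 4 fixed lists in each of the 22 libraries, by group; points are libraries, lines are group means, and open symbols mark the 3 libraries whose title and treatment tag differ. The B cell score lay between 3.4 and 3.65 in the 5 hypoxia ABT-263 libraries and between 4.06 and 4.38 in the 6 hypoxia vehicle libraries.

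The next comparisons asked whether ABT-263 altered the response to hypoxia. Hypoxia changed 6525 genes in ABT-263-treated mice, 2986 higher and 3539 lower (5649 to 6724 with each library left out). Olfr78 (4.67 ± 0.33), Ntrk2 (4.17 ± 0.16) and Ptx3 (3.63 ± 0.23) rose and Ankrd63 (−4.88 ± 0.23), Olfm2 (−3.45 ± 0.27) and Plvap (−2.29 ± 0.18) fell, as with vehicle. The 2 hypoxia comparisons share no library. Both called 1748 genes higher and 1653 lower, against 404 and 453 for independent lists, and 6 in opposite directions. Of the 4380 genes called with vehicle, 97.3% had the same sign with ABT-263, with a median ratio of log2 fold changes (ABT-263 over vehicle) of 1.01. Of the 6525 genes called with ABT-263, 95.5% had the same sign with vehicle, with a median ratio (vehicle over ABT-263) of 0.674, so the ratio depends on which comparison selects the genes. Bmpr2 fell (−0.61 ± 0.12) and Bcl2 rose (0.43 ± 0.09) here as well. Of 37 extracellular matrix genes 25 rose and 1 fell (adjusted p = 2.92e-17, and adjusted p = 0.206 with an estimated correlation), 22 of 23 B cell genes fell (adjusted p = 1.39e-15, and adjusted p = 0.18 with an estimated correlation), and 20 of 24 platelet and megakaryocyte genes fell while 2 rose (adjusted p = 1.05e-09, and adjusted p = 0.244 with an estimated correlation). Senescence-associated secreted factors were called as higher (21 of 49 higher, 8 lower, adjusted p = 0.0028, and adjusted p = 0.454 with an estimated correlation), and senescence regulators were not (5 of 18 higher, 2 lower, adjusted p = 0.835, and adjusted p = 0.95 with an estimated correlation). Club and secretory cell genes were lower in 12 of 22 cases, with Cyp4b1 at −1.10 ± 0.12 (adjusted p = 0.00036, and adjusted p = 0.355 with an estimated correlation).

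Skeletal muscle genes also passed as lower in this comparison, with Atp2a1 at −4.86 ± 1.35, Tnnt3 at −4.63 ± 1.41 and Mylpf at −4.16 ± 1.30, and 1 library decided these values. The muscle creatine kinase Ckm was at 464 CPM in normoxia ABT-263 replicate 2 and at 24 to 28.6 CPM in the other 5 libraries of that group. Without that replicate Mylpf stood at 0.162 (adjusted p = 0.502).

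The interaction of hypoxia and ABT-263 gave 0 genes with edgeR, 0 with limma-voom and 17 with DESeq2. At an unadjusted p under 0.05 edgeR had 1546 genes, against 832 by chance. The smallest p values were those of Gm3055 (1.47 ± 0.29), Kcnj13 (−0.66 ± 0.14), Ces2e (1.12 ± 0.24), Abcg3 (0.67 ± 0.14) and Pcx (−0.61 ± 0.13), each at an adjusted p of 0.286. Camera called 16 of 43 lists with its preset correlation, led by ciliated cell genes (median −0.40, adjusted p = 1.04e-09), and none with an estimated correlation (smallest adjusted p = 0.425). In simulated data for this comparison 43.3% of 1.5-fold, 74.2% of 2-fold and 92.3% of 4-fold changes were recovered. Without hypoxia ABT-263 replicate 1 the count was 2.

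Of the 89 genes that passed for ABT-263 in normoxia, 86.5% had the same sign in hypoxia. Both comparisons, which share no library, called 15 genes lower and 0 higher, where independent lists would share 0.132 and 0.0206.

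Changes under ABT-263 in hypoxia did not run against those of hypoxia across all genes. With the hypoxia vehicle libraries divided so that no library entered both contrasts, the correlation across 16638 genes between the hypoxia effect and the effect of ABT-263 in hypoxia averaged 0.13 over 20 divisions (0.0658 to 0.192), where a reversal would give a negative value. Genes are not independent replicates. With the same libraries in both contrasts the correlation was −0.00303. Simulations without any effect, of hypoxia or of ABT-263, averaged −0.452. Lacking a hypoxia effect, they do not give the correlation that an absent drug effect alone would leave. The covariance, which the spread of hypoxia effects does not rescale, was −0.000298, against a simulated mean of −0.0144. Without the 3 libraries with conflicting labels the divided libraries gave 0.126. Among genes called for hypoxia from a part of the libraries, a mean of 3000, 34.8% had the opposite sign under ABT-263.

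The last comparison set hypoxia with ABT-263 against normoxia with vehicle. It called 5704 genes, 2836 higher and 2868 lower (4863 to 5925 with each library left out). Of 23 B cell genes 22 fell, with a median of −1.49 and an adjusted p = 0.0151 with an estimated correlation. Cd79a (−1.97 ± 0.13) and Fcmr (−2.11 ± 0.16) were examples. Of 22 NK and cytotoxic genes 21 fell, among them Il2rb (−1.68 ± 0.17) (adjusted p = 2.08e-18, and adjusted p = 0.0772 with an estimated correlation). Of 40 cell cycle genes 29 rose, with Nusap1 at 2.01 ± 0.45 (adjusted p = 7.11e-08, and adjusted p = 0.553 with an estimated correlation). Of 24 p53 targets 12 rose and 1 fell, with the death receptor Fas at 0.62 ± 0.10 and the BCL-2 family member Bax at 0.41 ± 0.08 (adjusted p = 0.00546, and adjusted p = 0.108 with an estimated correlation). Hypoxia with vehicle already raised 6 of these 24 targets and lowered none (adjusted p = 0.0346, and adjusted p = 0.192 with an estimated correlation). Secreted factors of senescence rose in 21 of 49 cases and fell in 9 (adjusted p = 0.0132, and adjusted p = 0.495 with an estimated correlation), and senescence regulators were not called (adjusted p = 0.255, and adjusted p = 0.721 with an estimated correlation). Ntrk2 (3.71 ± 0.16), Hspa1b (4.18 ± 0.75), Cdkn1a (0.58 ± 0.17), Bcl2 (0.31 ± 0.09) and Bcl2l1 (0.36 ± 0.12) rose, Bmpr2 (−0.60 ± 0.12) and Plvap (−2.28 ± 0.18) fell, and Bcl2l2 (0.16 ± 0.11) did not pass.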

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

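The tests of residual blood, of NK cell genes and of mislabelled libraries were chosen after the results were seen. So were those of cell cycle genes in hypoxia libraries with low precursor genes and of the treatment of the 3 libraries with conflicting labels. The tests of lymph node stroma genes, of the relation to multiciliated precursors, erythroid precursors, time of day and other groupings of the libraries were written before their values were seen. The division of libraries by precursor score and the drug effect on the erythroid score were not part of them as written.

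Among 448 groups of 5 or 6 values, for genes, list scores and library measures named here, 25 had a library far from its group by Dixon's criterion, where chance gives about 1 in 20, or 22.4. The number is close to that given by chance, although several fell in the same libraries. In normoxia ABT-263 replicate 2 the skeletal muscle score was 8.17 (others 3.03 to 3.79), Atp2a1 518 CPM, Ckm 464 CPM, Mylpf 270 CPM, Tnnt3 463 CPM, Cd22 24.3 CPM (others 17.1 to 18.8), and mitochondrial transcripts took 5.72% of counts (others 4.37% to 4.75%). In normoxia ABT-263 replicate 6 the score of senescence regulators was 5.26 (others 5.07 to 5.13) and that of senescence-associated secreted factors 4.03 (others 3.71 to 3.81). In hypoxia ABT-263 replicate 4 the NK and cytotoxic score was 0.814 (others 1.47 to 1.71). That list shares no gene with the T cell list. In the same library Abcg3 was at 8.7 CPM, Bnip3 at 69.6 CPM, Klra9 at 0.495 CPM and Cyp1a1 at 42.6 CPM (others 2.31 to 4.99).

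Further single libraries stood apart. The alveolar macrophage score was 4.3 in normoxia ABT-263 replicate 3 (others 4.71 to 4.93), and the erythroid score was 5.48 in hypoxia vehicle replicate 1 (others 5.86 to 6.04). In CPM, Efnb2 was at 107 in hypoxia ABT-263 replicate 5, Fas at 75.6 in replicate 1 and Olfm2 at 0.818 in replicate 3. In hypoxia vehicle libraries Fst was at 10.5 in replicate 5 and Tagln at 886 in replicate 6. In normoxia vehicle libraries Bax was at 71.7 in replicate 1, Gm3055 at 2.25 and Rgs5 at 20.5 in replicate 2, and Tnfrsf10b at 5.3 in replicate 5.

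For 16 gene lists the effect of ABT-263 differed between oxygen conditions by camera's preset correlation. It was lower in hypoxia than in normoxia for ciliated cells (adjusted p = 1.04e-09), club and secretory cells (1.86e-05), platelets and megakaryocytes (6.42e-05), smooth muscle (9.6e-05), hypoxia-inducible factor targets (0.00187) and lipid and sterol synthesis (0.0111). It was higher for dendritic cells (1.74e-05), extracellular matrix (2.16e-05), T cells (2.16e-05), interferon response (2.16e-05), heat shock and unfolded protein response (0.000259), senescence-associated secreted factors (0.000948), ribosomal proteins (0.00311), NK and cytotoxic cells (0.00346), pan-endothelial genes (0.00909) and general capillary genes (0.0123). With an estimated correlation none was called (smallest adjusted p = 0.425), and fry called none either. Single genes were not called by edgeR, with 1546 at an unadjusted p under 0.05, and 14 of 100 groupings of the libraries gave as many (highest other 3136), so chance could not be excluded.

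B cell genes were lower with ABT-263 in both oxygen conditions, with an averaged drug effect of −0.603 ± 0.074 log2 units on their score, while the T and NK cell lists fell in normoxia (median log2 fold changes −0.531 and −0.74) and in the same direction in hypoxia (−0.287 and −0.475), where they lost the call with an estimated correlation (adjusted p = 0.399 for each, and 0.471 and 0.809 for the difference between oxygen conditions). Less residual blood is argued against, since the erythroid effect lay above the B cell effect by 0.603 ± 0.11. NK and cytotoxic genes changed by −0.592 ± 0.11, where less lymph node tissue would leave genes scarce in lymph nodes unchanged. The list covers cytotoxic cells as well as NK cells, and removing genes of the T cell list took none out. Its fall therefore does not decide on lymph node tissue. For B and T cell genes lymph node tissue stayed open: summed stroma genes lay above the B cell effect by 0.925 ± 0.19, but Cxcl13 alone gave 81.7% of their counts and 1 of the 5 genes had 10 counts in every library, so the limit set for this test was too weak. Wrong labels in the 3 conflicting libraries are not the whole source, because the B cell effect was −0.586 ± 0.079 without them. Their own B cell scores went with the titles. Normoxia ABT-263 replicate 1 was at 4.3 (normoxia vehicle 4.65 to 5.39). Hypoxia vehicle replicate 1 was at 4.38 and hypoxia ABT-263 replicate 1 at 3.65. The other hypoxia libraries had 4.06 to 4.28 with vehicle and 3.4 to 3.59 with ABT-263. This argues against the tag's treatment for these 3 libraries. A loss of B cells that depend on BCL-2 may underlie the B cell part, as a hypothesis that was not tested. Cell numbers were not measured here, and the hypothesis leaves out the T and NK cell lists.

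Cell cycle genes were higher in all 5 hypoxia ABT-263 libraries (score 3.07 to 4.22) than in the 6 hypoxia vehicle libraries (2.4 to 2.91), and in normoxia in ABT-263 replicates 1, 2 and 6 (3.05, 4.32 and 4.29) but not 3 to 5 (2.01 to 2.11, vehicle 2.05 to 2.65). Multiciliated precursors are argued against as the whole source in hypoxia, since the 3 ABT-263 libraries with low precursor scores (2.45 to 2.6, vehicle 2.12 to 3.11) exceeded the 6 vehicle libraries in cell cycle score by 0.69 ± 0.16. Over all libraries the score moved with that of other multiciliated precursor genes within groups (r = 0.743, permutation p = 0.013, adjusted p = 0.039 over 3 relations, Spearman's rho = 0.706, permutation p = 0.0083, r = 0.707 without the 2 farthest libraries). This met the limit set before its values were seen. The libraries fall into 2 clusters, however, 5 high ABT-263 libraries and 17 others. Within the larger cluster r was −0.16 (permutation p = 0.6, rho = 0.0098). That division was not part of the prediction, and it narrows the precursor score to 2.12 to 3.11, where the high libraries had 3.65 to 4.47. Neither value decides whether precursors could contribute, and in normoxia they stayed open. For dividing erythroid precursors the relation within groups did not decide (r = 0.297, permutation p = 0.35, rho = 0.0785, permutation p = 0.76, and r = 0.00213 without the 2 farthest libraries). Averaged over oxygen conditions, ABT-263 changed the erythroid score by −0.000102 ± 0.084 and the cell cycle score by 0.812 ± 0.27. The erythroid score includes globins, which residual blood also carries, so a few dividing precursors might not move it. Klf1, Rhag and Hemgn had too few counts to be tested. These values therefore do not decide on such precursors either.

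Hspa1b was raised in 4 of 5 hypoxia ABT-263 libraries and not in replicate 1, a library with conflicting labels. That this library came from a vehicle-treated mouse is argued against by its B cell score, −0.401 log2 units from the lowest hypoxia vehicle library (SD of that group 0.14). A different time of day at collection may contribute and stayed open. The clock phase measure differed between the hypoxia groups by 0.283 ± 0.27 log2 units, which neither shows nor excludes a shift. The measure was also mostly higher in hypoxia than in normoxia libraries. With vehicle it lay between −0.661 and 0.569 in normoxia and between −0.0281 and 1.5 in hypoxia. With ABT-263 it lay between −0.74 and 0.656 in normoxia and between 0.674 and 1.51 in hypoxia. The core clock list was not called for hypoxia with vehicle (2 of 18 higher, 2 lower, adjusted p = 0.778). Whether time of day entered the hypoxia comparisons was not tested.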

How the results depend on the processing

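The alternatives that leave out normoxia ABT-263 replicates 2 and 6 together, leave out each replicate in the list tests, or use the same libraries in both contrasts were chosen after the data were examined. No paired analysis was possible because replicate numbers pair no samples. No cause was tested except where named.

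Calls for hypoxia with vehicle were more stable than those for ABT-263. Of 99 named calls for hypoxia with vehicle, 98 held with every single library left out, as did 46 of 54 for hypoxia with ABT-263, where 3 muscle genes reversed, against 1 of 32 for ABT-263 in normoxia, 2 of 27 in hypoxia and 22 of 40 averaged. Requiring 2-fold changes left 435 genes for hypoxia with vehicle, 4 for ABT-263 in normoxia, 10 in hypoxia, 552 for hypoxia with ABT-263, 57 for ABT-263 averaged and 762 for hypoxia with ABT-263 against control. The share of same signs in the 2 hypoxia comparisons was 96.2% to 98.4% with each library left out.

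ABT-263 counts moved most. By their B cell scores the 3 conflicting libraries went with their titles, not with the tags. In normoxia the counts were 324 with DESeq2, 59 with library totals and 17 with the compared groups only. They were 16 without the 3 conflicting libraries, 0 by the tag (1386 at an unadjusted p under 0.05), 147 without replicates 2 and 6, and 1 to 183 with each library left out. The cell cycle median became −0.00728 without replicates 2 and 6 (adjusted p = 0.889).

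In hypoxia the ABT-263 counts were 247 with DESeq2, 9 with limma-voom, 152 with the compared groups only, 77 without the 3 libraries, 0 by the tag (1650 at an unadjusted p under 0.05), 257 without replicates 2 and 6, and 3 to 228 with each library left out.

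Averaged, they were 793 with DESeq2, 253 with limma-voom, 271 with library totals, 257 without a filter, 0 by the tag (1916 at an unadjusted p under 0.05), and 164 to 649 with each library left out. The interaction gave 17 with DESeq2, 1 without the 3 libraries, 8 without replicates 2 and 6, and 0 to 2 with each library left out.

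In the order of the contrasts, camera with an estimated correlation called 2, 3, 1, 0, 0, 4 and 2 lists, against 20, 16, 12, 15, 16, 14 and 20 with the preset one. The order was hypoxia with vehicle, ABT-263 in normoxia and in hypoxia, hypoxia with ABT-263, interaction, ABT-263 averaged, and both against control. Fry called 4 for ABT-263 in normoxia, 1 in hypoxia, 5 averaged and 0 for the interaction. For hypoxia with vehicle fry called every list that the preset correlation called, except 4: pan-endothelial (adjusted p = 0.0628), ribosomal protein (0.0628), heat shock (0.114) and oxidative phosphorylation genes (0.158). Its adjusted p was 5.9e-06 for pericytes, 2.12e-05 for smooth muscle, 0.000681 for extracellular matrix and 1e-05 for B cells.

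For hypoxia with ABT-263, 3 muscle genes reversed without normoxia ABT-263 replicate 2, and without 2 and 6: Mylpf to 0.162 and 0.082, Neb to 0.756 and 0.855, and Tnni2 to 0.679 and 0.75. With other libraries left out their values reached −4.42 for Mylpf, −3.75 for Neb and −3.66 for Tnni2. The correlation of hypoxia and ABT-263 effects was 0.233 for genes called in a part of the libraries and −0.00303 with the same libraries in both contrasts, where shared libraries lower it by construction.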

Other observations

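Other groupings of the libraries were written as a test before their values were seen, with 100 groupings per contrast, the real one included. For hypoxia with vehicle 1 grouping, the real one, gave as many as 4380 genes (highest other 1964), and for hypoxia with ABT-263 likewise 1 gave 6525 (highest other 5823). For ABT-263 in normoxia 2 gave 89 or more (highest other 100). For ABT-263 in hypoxia 1 gave 50 (highest other 20), for ABT-263 averaged 1 gave 423 (highest other 2), and for hypoxia with ABT-263 against control 1 gave 5704 (highest other 1778). For these 6 counts the share of groupings with as many was under 0.05, without adjustment over contrasts. The highest other counts of 1964 and 5823 came from groupings that gave 10 libraries another group, nearly swapping the 2 groups. The 100 for ABT-263 in normoxia came from a grouping that moved 2 libraries.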
